A study of Mus musculus with 6 samples.

How the data were processed

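Gene expression was measured in primary megakaryocytes, the platelet-forming cells, grown from mouse fetal livers at embryonic day 13.5. The p45-/- group lacked p45, the large subunit of the transcription factor NF-E2 that the gene Nfe2 encodes, and the WT group was wild type. Each group held 3 samples on the C57BL/6 background, from independent experiments according to the series' design. The labels' source field gives cultured megakaryocytes, while the labels' extraction protocol speaks of whole embryos as the origin of the RNA. The samples are called megakaryocyte cultures here after the source field, and the contradiction is not resolved.

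Per the labels' protocols, total RNA was amplified and labelled with Cy3, and each sample was hybridised to a single-colour Agilent array. Per the file headers, the spot intensities were extracted with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name 10.1. Per the file headers, the deposited processed intensity of a spot is background-subtracted and spatially detrended within its array, on a linear scale and not scaled between arrays. The series' value table held the same processed intensities as deposited by the authors, linear and not centred by gene, with a largest difference of 0.497% from rounding. Its column medians lay between 20.9 and 42.0, and it has no direction to settle because the arrays have 1 channel.

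From these intensities, log2 values were taken and each array's 75th percentile over its non-control probes was subtracted. Control spots were left out, spots flagged as non-uniform or as population outliers (32 to 80 per array) were set to missing, and spots of the same probe were averaged. No spot was saturated, and the extraction software's quality metrics were all in range except on WT array 2. A probe was kept if it was well above background on all arrays of at least 1 group, which left 23958 of 41174 probes. Probe names came from RefSeq accessions matched without versions to a gene table of assembly GRCm38.p6, used for names only. A symbol was found for 26682 probes, covering 18213 symbols, and 14492 probes kept their accession. Each gene was represented by its probe with the highest mean level over all 6 arrays, giving 18211 genes, of which 12945 had a symbol.

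Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No block was used, with 4 residual degrees of freedom. Log2 differences are p45-/- minus WT, so negative values are lower in the arrays labelled p45-/-. Where a probe was not well above background on any array of a group, the fold is a bound, "at least N-fold". It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. With 3 arrays against 3 an exact permutation test cannot go below p = 0.1. The number of arrays limits the precision of every value.

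The replicate numbers 1 to 3 occur in both groups. Over the genes tested, the deviations from the group means of same-numbered arrays correlated at 0.647, 0.589 and 0.270 for numbers 1, 2 and 3. Replicate 3 of p45-/- correlated more with WT replicate 2, at 0.616, than with its own number. All 3 same-numbered values are above 0.1, the limit set for pairing, so the numbers were taken to pair the samples, from the data and not from a statement in the labels. Deviations within a group cancel out, so outlying replicate 1 arrays in both groups would also raise the values of the other numbers. The check therefore cannot tell a shared experiment from array quality or slide. The fit with the replicate number as a block, with 2 residual degrees of freedom, is given beside a result where it changes the call. Replicate 3 of both groups lay on slide 1 and the other 4 arrays on slide 2. Each slide was scanned in a scan of its own, so slide and scan are the same batch.

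Before the data were examined, 32 gene lists with 694 entries were written down, of which 665 were found on the array by name. Tubb1 was among those not found. The lists with at least 3 tested genes, 31 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with the correlation estimated from the arrays. Also fixed then were the named genes: Nfe2, the 10 genes in each direction with the largest change among called genes whose groups do not overlap and that were well above background in the higher group, filled up by smallest unadjusted p where fewer passed, and up to 4 called members of each list or, where none was called, the 2 with the smallest unadjusted p. Genes named outside this rule are said to be so, and some genes the rule names are not reported here. The alternatives were the replicate or slide as a block, values within a slide, normexp background correction with an offset of 50, quantile normalization, median scaling, the series' value table, other filters and probe summaries, eBayes with a trend and robust, array weights, leaving out each array, other thresholds, and other list tests. The planned normexp correction was run on median spot signals, the columns used here.

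The fits were tested on simulated data with the arrays' own gene means and spreads, for p45-/- against WT over 18204 genes with 200 changed genes and 5 simulations. With pair effects as in the arrays, the unblocked fit recovered 6.4% of genes changed 4-fold, 58.0% of those changed 16-fold and 78.8% of those changed 64-fold. With the replicate block these shares were 4.0%, 59.6% and 78.4%. With no pair effects simulated they were 20.0%, 69.2% and 88.0% without the block and 0%, 15.6% and 60.4% with it. A list shifted by 1 log2 unit, the erythroid markers, was called in all 5 simulations at the preset correlation, with or without pair effects and the block. Apart from the pair effects the simulated genes varied independently, while the lists' median estimated correlation in the arrays was 0.454. The simulations therefore do not test the preset correlation for lists whose genes vary together. With an estimated correlation and no block it was called in 4 of the 5 simulations with pair effects and in 1 of the 5 without them, and with an estimated correlation and the replicate block in 0 of either. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.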

Results

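The expression of 18211 genes was compared between 3 megakaryocyte cultures labelled p45-/- and 3 WT cultures, on 6 single-colour arrays. The comparison asks which transcripts differ in megakaryocytes that lack the large subunit of NF-E2. The 75th percentile of the processed signal was 135, 407 and 589 on p45-/- arrays 1, 2 and 3, and 339, 583 and 575 on WT arrays 1, 2 and 3. Between 57.8% and 64.8% of the probes were well above background on an array. The spike-in E1A probes had their lowest median signal, 3073, on p45-/- array 1, close to the 3125 of WT array 3, while the 75th percentile of p45-/- array 1 lay far below that of WT array 3. The highest spike-in median was 9181, on p45-/- array 2.

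Across the genes tested, p45-/- array 1 stood apart from the others. Its Pearson correlation with them lay between 0.782 and 0.884, while the others correlated with each other at 0.941 to 0.984. These are correlations across genes, which are not independent replicates. The first principal component held 72.2% of the variance and placed p45-/- array 1 at -184.3, with the other arrays between -25.3 and 113.4. On the second component, with 11.6% of the variance, the p45-/- arrays lay at 0.66 to 49.1 and the WT arrays at -59.2 to -13.0.

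**Figure D1:**
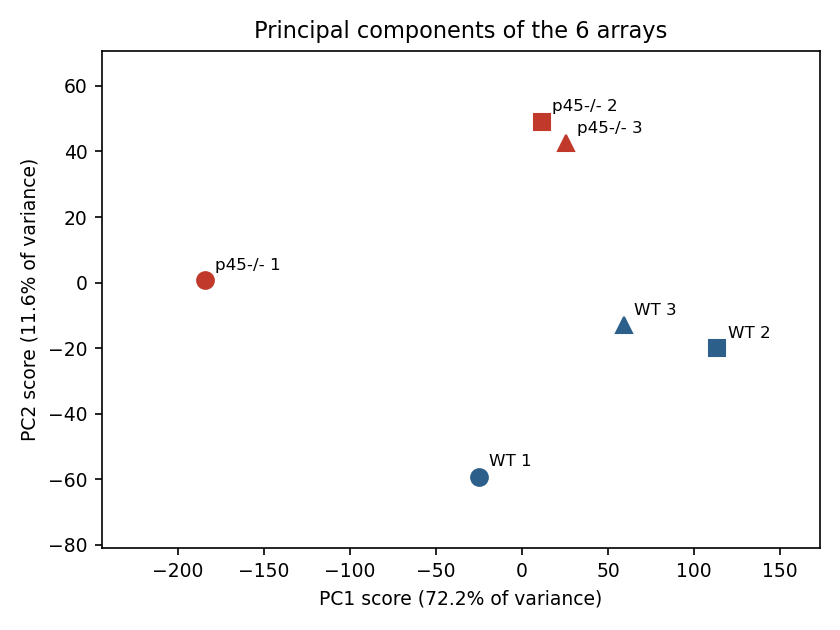
Principal component scores of the 6 arrays over the genes tested, PC1 (72.2% of variance) against PC2 (11.6%), with colour for genotype and symbol shape for replicate number. Replicate 1 of p45-/- lies at -184.3 on PC1, far from the others, and the p45-/- arrays lie above the WT arrays on PC2.

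Nfe2, the gene that encodes p45, was read by 1 probe that was well above background on all 6 arrays. Its log2 level was 5.88 ± 0.88 (SD, n = 3) in p45-/- and 6.05 ± 0.71 (SD, n = 3) in WT. The difference was -0.17 (SE 0.57, 95% interval -1.53 to 1.19, limma adjusted p = 0.923), and an exact permutation test gave p = 0.7, two-sided, where 0.1 is the smallest p possible. With slide as a block the difference was the same, within slide 2 it was -0.26 and within slide 1, with 1 array per group, 0.0041. It was 0.17 with quantile normalization and -0.68 with median scaling, which moved the median of all genes to -0.56. The position of the probe relative to the deleted part of the gene is not known here, so this level does not check the genotype labels. For this reason directions below refer to the arrays labelled p45-/-.

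Transcripts of the serotonin transporter, of a tubulin tyrosine ligase-like gene and of platelet receptors were among those with large losses in the arrays labelled p45-/-. With the replicate number as a block, 5 genes fell and 0 rose. Gp6, the platelet collagen receptor glycoprotein VI, fell by 6.09 on the log2 scale (SE 0.30, adjusted p = 0.0167), a 68.2-fold difference. Clec1b, which encodes the platelet receptor CLEC-2, fell by 4.53 (SE 0.35, adjusted p = 0.0454) from 6.15 ± 1.35 (SD, n = 3) in WT to 1.62 ± 0.83 (SD, n = 3). Slc6a4, the serotonin transporter, fell by 6.88 (SE 0.47, adjusted p = 0.0383). Ttll11, of the tubulin tyrosine ligase-like family, fell by 6.19 (SE 0.43, adjusted p = 0.0383) and was well above background on 2 of the 3 p45-/- arrays. Fam131a fell by 4.07 (SE 0.31, adjusted p = 0.0454). Clec1b and Fam131a lie outside the naming rule and were chosen after their values were seen.

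Without the block limma called 0 genes, with a smallest adjusted p of 0.0877, and these 5 genes had adjusted p of 0.0877 (Ttll11), 0.274 (Slc6a4), 0.288 (Gp6) and 0.331 (Clec1b and Fam131a). At an unadjusted p under 0.05 there were 478 higher and 606 lower genes, against 911 genes at that level by chance, and with the block 2613 higher and 1086 lower, which turns the balance. The groups did not overlap for 870 higher and 1537 lower genes, 13.2% of those tested, where chance gives 10%. Of these, 144 higher and 84 lower genes differed at least 4-fold, so the larger differences leaned the other way. With slide as a block and within slide 2 the count stayed at 0. Without WT replicate 1 it was 1 gene, Ttll11, and with array weights, which gave p45-/- array 1 a weight of 0.0979, it was 505. Leaving out replicate 1 of both groups, chosen after seeing the data, gave 24 genes without the block, all 5 above among them, and 0 with it. The blocked count depended on the scaling and on the variance prior, from 0 with quantile normalization to 1590 with median scaling.

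**Figure D2:**
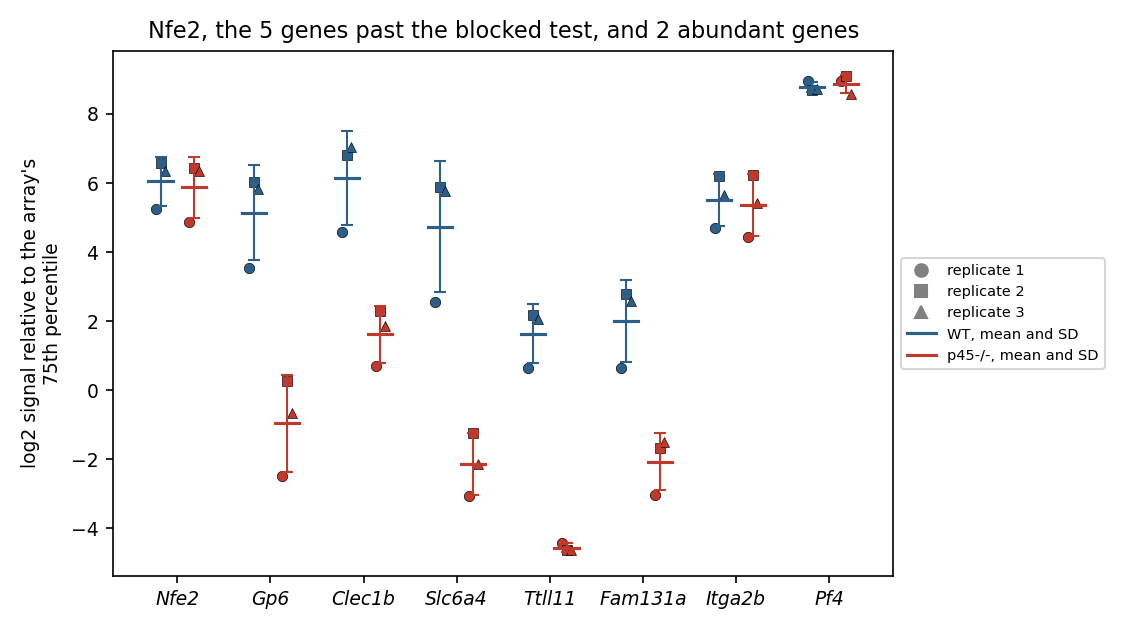
Log2 signal relative to the array's 75th percentile for Nfe2, the 5 genes that passed the blocked test, and the abundant megakaryocyte genes Itga2b and Pf4. Symbols are single arrays by replicate number, and lines and bars are the mean and SD of 3 arrays. Gp6, Clec1b, Slc6a4, Ttll11 and Fam131a are lower on every p45-/- array than on any WT array, while Nfe2, Itga2b and Pf4 overlap.

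Among the genes named by the rule, which did not pass the unblocked test and are given as values, Tbxas1, thromboxane A synthase, had a log2 difference of -4.13 (SE 0.47, adjusted p = 0.206, and 0.0512 with the replicate block). Mpig6b, an inhibitory platelet receptor, was not well above background on any p45-/- array and was at least 14.7-fold lower there (adjusted p = 0.220). Phgr1 was at least 4.29-fold lower and Abcg5, a sterol transporter subunit, at least 2.55-fold lower on the same terms, with adjusted p of 0.246 and 0.262. The log2 differences of Tmem125, Il12rb1 (an interleukin 12 receptor subunit) and Dnah11 (an axonemal dynein) were -2.62, -2.44 and -3.12. Tmem125 was well above background on 2 of the 3 p45-/- arrays and Dnah11 on 1. On the higher side, Tmem184a had a log2 difference of 4.77 (SE 0.54, adjusted p = 0.206), Matn1, a cartilage matrix protein, 3.37 (SE 0.28, adjusted p = 0.0877), Trim10, an erythroid gene, 3.22 and Prelp, an extracellular matrix protein, 3.03. Arhgef28, Nat8, Efna5, Gdf3, Mboat2 and Tmod1 had differences of 2.73, 2.61, 2.32, 2.13, 2.09 and 2.07, with Nat8 well above background on 1 of the 3 WT arrays. Each of these 10 higher genes was higher on every p45-/- array than on any WT array, which the naming rule requires.

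Genes of platelet function were lower as lists in the p45-/- arrays at the preset correlation, and none of these calls held with an estimated correlation. In the same arrays the erythroid markers had a median of 1.52. The 5 tested genes reported earlier as p45 targets were all lower in group mean, with a median of -1.40 (camera adjusted p = 8.14e-05, adjusted p = 0.481 with an estimated correlation) and 2 past the threshold adjusted over the list alone, Tbxas1 and Hsd3b1, a steroid dehydrogenase at -3.65 (SE 1.01). Hsd3b1 differed by -0.72, -5.00 and -5.23 in pairs 1, 2 and 3. It was well above background on 2 of the 3 p45-/- arrays. Casp12 was higher by 0.27 in pair 1, and the groups did not overlap for 2 of the 5 genes. Of 24 platelet surface receptors, 22 were lower with a median of -0.58 (adjusted p = 5.44e-05, adjusted p = 0.481 with an estimated correlation). For this list 0 genes passed over all genes tested and 4 when adjusted over the list alone, and with the replicate block 2 and 5. Itga2b and Itgb3, the subunits of the fibrinogen receptor, differed by -0.15 (SE 0.59) and -0.29 (SE 0.39), Gp1ba by -0.53 and Gp9 by -0.74. These 4 receptor genes lie outside the naming rule and were chosen after their values were seen. In platelet signalling and eicosanoid synthesis 34 of 38 genes were lower, with a median of -0.56 (adjusted p = 5.42e-06, adjusted p = 0.481 with an estimated correlation), 1 of them past the threshold adjusted over the list alone, Tbxas1, which the list of p45 targets also holds. The ADP receptor gene P2ry12 differed by -2.45 (SE 0.65) and was well above background on 2 of the 3 p45-/- arrays. In the cytoskeleton of proplatelet formation 27 of 29 genes were lower, with a median of -0.73 (adjusted p = 2.55e-08, adjusted p = 0.481 with an estimated correlation), among them the tubulin genes Tuba8 at -1.72 and Tuba4a at -1.50. In granule biogenesis and secretion 25 of 28 were lower, with a median of -0.43 (adjusted p = 0.000155, adjusted p = 0.481 with an estimated correlation), with Vps33b at -1.66 and Lyst at -0.95. The medians of this list were -0.94, -0.18 and -0.19 in the pairs with replicate numbers 1, 2 and 3. The alpha granule contents did not pass, with a median of -0.18 (adjusted p = 0.235), and passed as lower without p45-/- replicate 2 (adjusted p = 0.0371) or WT replicate 1 (adjusted p = 0.0302). In that list F13a1 differed by -1.001, Cxcl5 by 1.60 and Pf4, which lies outside the naming rule as well, by 0.082 (SE 0.29). With the replicate block the genes past the threshold adjusted over the list alone were 3 lower among the p45 targets, 6 lower and 1 higher in signalling, 6 lower in the cytoskeleton, 2 lower in granule biogenesis and 1 lower among the alpha granule contents, and 0 of these lists' genes outside the surface receptors passed over all genes.

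Among regulators, 16 of 18 megakaryocyte transcription factors were lower, with a median of -0.44 (adjusted p = 0.000598, adjusted p = 0.501 with an estimated correlation, adjusted p = 0.0520 with quantile normalization). Gata2 at -1.98 (SE 0.42) and Ets1 at -1.39 (SE 0.33) passed the threshold adjusted over the list alone, and 0 passed over all genes. Of the 10 CNC and small Maf factors and their regulators, relatives and partners of p45, 9 were lower with a median of -0.38 (adjusted p = 0.00985, adjusted p = 0.481 with an estimated correlation), 1 of them past the threshold adjusted over the list alone, and an adjusted p of 0.0585 leaving out replicate 1 of both groups. The medians of this list were -0.94, -0.12 and -0.079 in pairs 1, 2 and 3. Mafg, a small Maf partner, differed by -1.29 (SE 0.27) and Keap1 by -0.81. Of 38 Nrf2 target cytoprotective genes, 29 were lower with a median of -0.25 (adjusted p = 0.000961, adjusted p = 0.481 with an estimated correlation), with Gsr at -1.31 and Esd at -1.31. Their medians were -0.63, -0.26 and 0.0054 in pairs 1, 2 and 3. All 9 genes of NADPH production and the pentose phosphate pathway were lower, with a median of -0.43 (adjusted p = 0.00515, adjusted p = 0.481 with an estimated correlation), Taldo1 at -0.90 and G6pdx at -0.80. All 32 proteasome subunit genes were lower, with a median of -0.32 (adjusted p = 7.94e-05, adjusted p = 0.521 with an estimated correlation, adjusted p = 0.549 with quantile normalization), Psmd11 at -0.75 and Psma6 at -0.71. Their medians were -0.76, -0.16 and -0.14 in pairs 1, 2 and 3. In haem synthesis and iron handling 17 of 24 genes were higher, with a median of 0.25 that did not pass (adjusted p = 0.0757) and passed with quantile normalization (adjusted p = 0.00178) and without p45-/- replicate 1 (adjusted p = 0.00297). Alas2, the erythroid enzyme that starts haem synthesis, differed by 4.36 (SE 1.08) and Abcb10 by 0.80. In the fit with the replicate block 3 transcription factors and 5 Nrf2 targets were lower and 1 gene of haem synthesis higher past the threshold adjusted over the list alone, and 0 over all genes.

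Several cell cycle and stress lists were also lower at the preset correlation, and none of these calls held with an estimated correlation. All 31 genes of mitosis and cytokinesis were lower, with a median of -0.35 (adjusted p = 7.94e-05, adjusted p = 0.481 with an estimated correlation), Incenp at -0.59 and Anln at -0.66. Of 29 genes of DNA replication and S phase, 27 were lower with a median of -0.24 (adjusted p = 0.0158, adjusted p = 0.546 with an estimated correlation), E2f1 at -0.43 and Dut at -0.42, and the median was 0.023 with quantile normalization. This call was lost without p45-/- replicate 2 (adjusted p = 0.0750) or WT replicate 2 (adjusted p = 0.164). The cell cycle inhibitors and D cyclins did not pass (median -0.16, adjusted p = 0.595), Cdkn1b at -0.37 and Rb1 at -0.63. Among apoptosis regulators 21 of 22 were lower, with a median of -0.55 (adjusted p = 4.95e-05, adjusted p = 0.481 with an estimated correlation), Bbc3 at -0.91 and Casp12 at -1.40. The medians of this list were -0.99, -0.23 and -0.28 in pairs 1, 2 and 3, and 9 of its 22 genes were lower in all 3 pairs. Of 21 genes of the unfolded protein and integrated stress response, 18 were lower with a median of -0.48 (adjusted p = 0.00272, adjusted p = 0.481 with an estimated correlation, adjusted p = 0.225 with quantile normalization), Edem1 at -1.16 and Pdia4 at -0.76. All 18 interferon response genes were lower, with a median of -1.08 (adjusted p = 1.66e-06, adjusted p = 0.481 with an estimated correlation), Usp18 at -1.65 and Ddx58 at -0.95. Their medians were -2.10, 0.072 and -1.10 in pairs 1, 2 and 3, and WT array 1 lay 2.03 above the other WT arrays. All 18 glycolysis genes were lower, with a median of -0.51 (adjusted p = 4.95e-05, adjusted p = 0.481 with an estimated correlation), led by the glucose transporter genes Slc2a3 at -1.61 and Slc2a1 at -0.89. The inflammatory cytokines and chemokines (median -0.42, adjusted p = 0.0688), with Tnfaip3 at -0.90 and Il1b at -1.15, did not pass, and passed as lower without p45-/- replicate 1, WT replicate 2 or WT replicate 3 (adjusted p = 0.0185, 0.00231 and 0.0212). Cholesterol synthesis did not pass either (median -0.35, adjusted p = 0.169), and passed with the replicate block (adjusted p = 0.00381, adjusted p = 0.509 with the block and an estimated correlation). It also passed without p45-/- replicate 2, p45-/- replicate 3 or WT replicate 1 (adjusted p = 0.0180, 0.0234 and 0.000113). The 13 tested genes next to Nfe2 on chromosome 15 did not pass as a list (median -0.22, adjusted p = 0.13), though 12 of them were lower, with Nckap1l at -1.03. The 1 higher gene was Ppp1r1a at 1.54, well above background on 1 of the 3 WT arrays. In the blocked fit 1 interferon response gene and 1 glycolysis gene were lower past the threshold adjusted over the list alone, and 0 over all genes.

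Markers of other blood and liver cell types differed in both directions. Of 24 erythroid markers, 21 were higher in the p45-/- arrays, with a median of 1.52 (adjusted p = 3.07e-08, adjusted p = 0.105 with an estimated correlation). With limma's fry, which tests whether a list moves on balance 1 way, the adjusted p was 0.0327, and 0.0574 with the replicate block. Past the threshold adjusted over the list alone were 7 erythroid markers, and 0 passed over all genes. Trim10 differed by 3.22 (SE 0.47), while Hba-a1, an alpha globin gene whose transcript near-identical copies share, differed by 0.56 (SE 0.97) and Epor by -0.20, both chosen outside the naming rule after their values were seen. Of 16 hepatoblast and hepatocyte markers, 15 were higher with a median of 0.92 (adjusted p = 0.000150, adjusted p = 0.481 with an estimated correlation), Apob at 1.19 and Apoh at 1.27, and pair medians of -0.32, 1.41 and 1.78. The stromal and fibroblast markers had a median of 0.56 (adjusted p = 0.0192, adjusted p = 0.546 with an estimated correlation, adjusted p = 0.0845 with the replicate block, adjusted p = 0.205 with quantile normalization). Without p45-/- replicate 2, p45-/- replicate 3 or WT replicate 3 its median was 0.40, 0.19 and 0.42, and its adjusted p was 0.197, 0.649 and 0.0534. In that list Fbn1 differed by 0.98 and Acta2 by -0.81, and the probes of Acta2 disagreed, from -0.81 to 1.05. Of 17 neutrophil markers, 16 were lower with a median of -0.81 (adjusted p = 5.42e-06, adjusted p = 0.481 with an estimated correlation), 2 of them past the threshold adjusted over the list alone, the protease genes Ctsg at -1.26 and Mmp8 at -1.79. Of 14 mast cell and basophil markers, 10 were lower with a median of -0.86 (adjusted p = 0.00893, adjusted p = 0.481 with an estimated correlation), with Gzmb, well above background on 2 of the 3 p45-/- arrays, at -2.76. The 1 gene of this list past the threshold adjusted over the list alone was Slc6a4, which platelets also carry, and without p45-/- replicate 1 the list did not pass (median -0.33, adjusted p = 0.0695). The macrophage (median -0.11, adjusted p = 0.845), stem and progenitor (median -0.40, adjusted p = 0.117), endothelial (median 0.29, adjusted p = 0.235) and lymphoid markers (median 0.64, adjusted p = 0.0699) did not pass, and the lymphoid markers passed without WT replicate 1 (adjusted p = 0.00354). In these lists Timd4 differed by 1.56, Siglec1 by -1.04, Sox4 by 1.04, Myb by -1.05, Stab2 by 1.05, Tie1 by 0.82, Ebf1 by 2.03 and Cd3d by 0.78. The Ebf1 difference was 4.38, 1.09 and 0.63 in pairs 1, 2 and 3. Ebf1 and Timd4 were well above background on 2 of the 3 WT arrays. With the replicate block 16 erythroid markers were higher and 1 lower past the threshold adjusted over the list alone, as were 3 neutrophil, 7 mast cell and 4 stem cell markers on the lower side, and over all genes only Slc6a4.

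**Figure D3:**
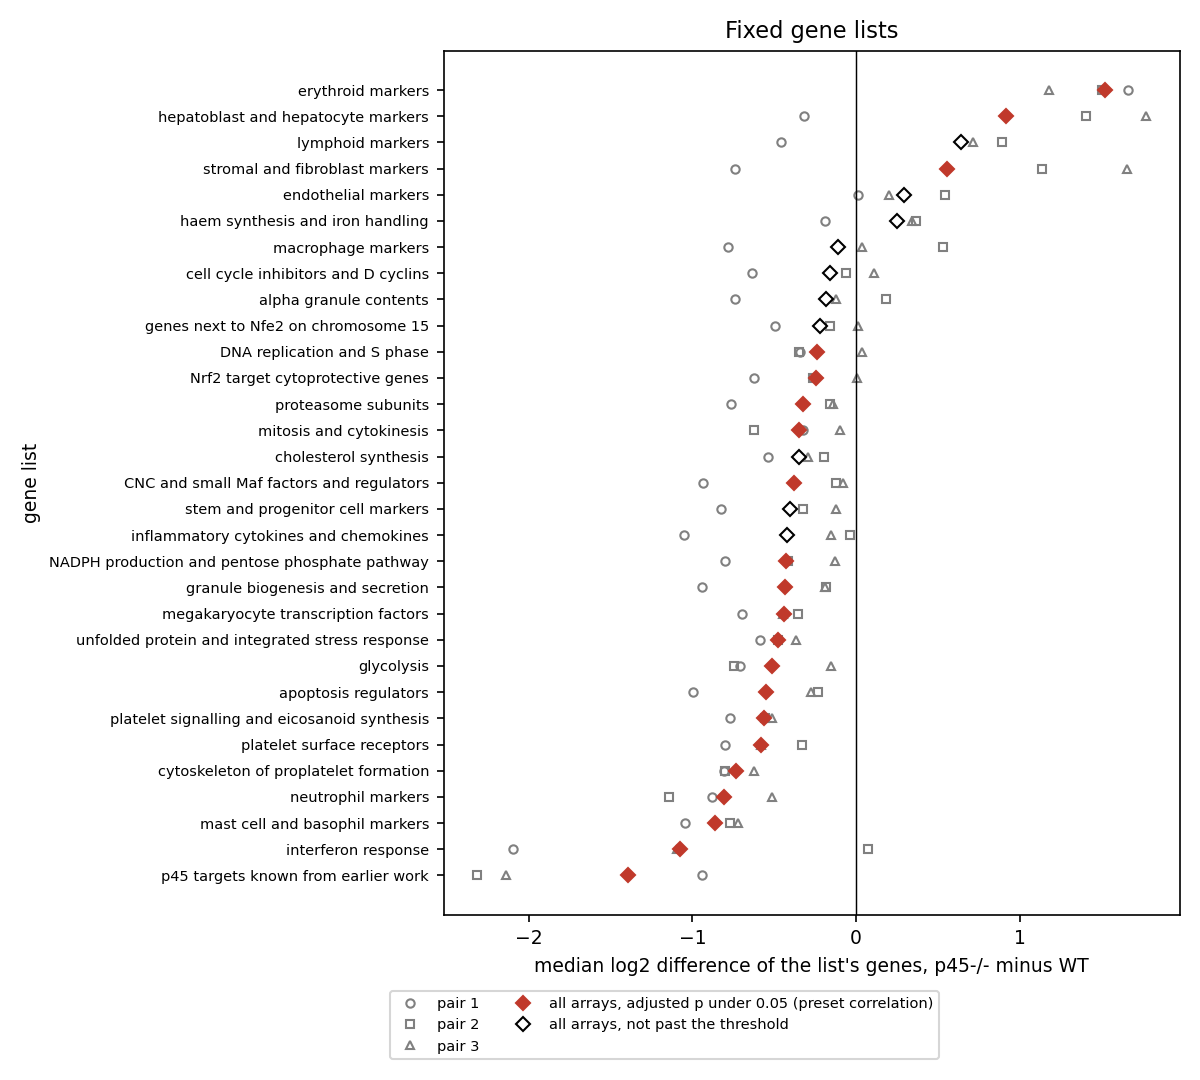
Median log2 difference, p45-/- minus WT, of each of the 31 tested gene lists over all arrays (diamonds, filled where camera's adjusted p at the preset correlation was under 0.05) and in each same-numbered pair of arrays (open grey symbols). The erythroid markers lie highest at 1.52 and the known p45 targets lowest at -1.40, and 0 lists passed with an estimated correlation.

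**Figure D4:**
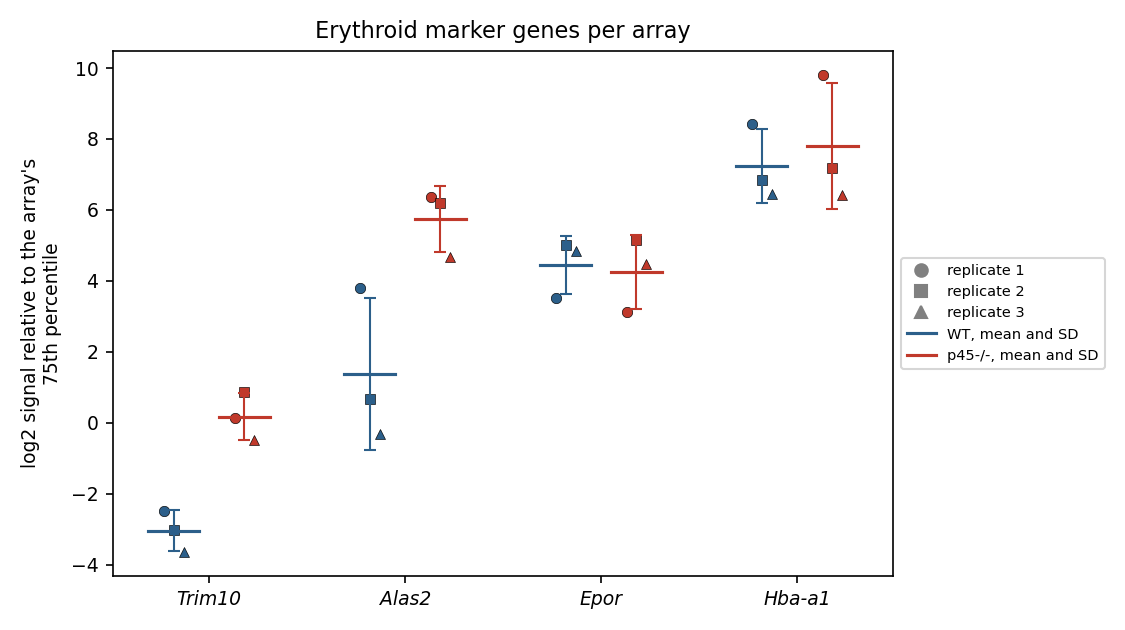
Log2 signal relative to the array's 75th percentile of 4 erythroid genes, with single arrays as symbols by replicate number and the mean and SD of 3 arrays as lines and bars. Trim10 and Alas2 are higher on every p45-/- array than on any WT array, while Epor and Hba-a1 overlap.

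In total camera called 18 lists lower and 3 higher of 31 at the preset correlation, and 0 with an estimated correlation, where the erythroid markers had the smallest adjusted p of 0.105. With slide as a block all 21 calls kept their direction and stayed past the threshold. Within slide 2 this held for 20 of the 21, all but the stromal and fibroblast markers at a median of 0.0017, and within slide 1, with 1 array per group and no test, 19 medians had the same sign, all but the Nrf2 targets at 0.0054 and DNA replication at 0.036.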

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

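Settings that leave out replicate 1 or 2 of both groups, those that join the replicate block with another choice, and those that exchange the prior, were chosen after seeing the data. The number of genes past the threshold was 0 without the block. It stayed at 0 with slide as a block, within slide 2, with normexp, quantile normalization, the series' value table, either other filter, outlier-flagged spots kept, the mean of a gene's probes, every probe on its own, a 2-fold limit and a threshold of 0.01. It was 5 with the replicate block, 10 (all lower) with median scaling, 1 with trend and robust, 505 (259 higher, 246 lower) with array weights, 2 at a threshold of 0.1, and 0 to 1 when any array was left out. Leaving out replicate 1 of both groups gave 24, 6 higher and 18 lower. Median scaling moved the median of all genes to -0.56, from -0.048.

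With the replicate block the count was 0 after quantile normalization, 3 without a filter, 286 (84 higher, 202 lower) with trend and robust, 287 (125 higher, 162 lower) with normexp and 1590 (823 higher, 767 lower) with median scaling. It was 2429 (2211 higher, 218 lower) within slide 2, 476 (378 higher, 98 lower) leaving out replicate 2 of both groups and 0 leaving out replicate 1 of both. With the prior degrees of freedom of the 75th percentile scaling, the quantile fit called 112 (34 higher, 78 lower), and with those of the quantile fit, the 75th percentile scaling called 0. The degrees of freedom limma gave the variance prior went with this in part, at 4.05 for the block, 2.04 with quantile normalization, 6.92 with trend and robust and 20.4 with normexp, and infinite in the fits that called 1590, 2429 and 476. Without a filter they were 4.7, above those of the block, while fewer genes were called. The block changed no other call than those given with the results.

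The Nfe2 difference, never past the threshold, was 0.17 with quantile normalization, -0.68 with median scaling, -0.35 with normexp, 0.021 with array weights and 0.0041 within slide 1, and -0.57 to 0.34 when any array was left out. The number of shifted lists, 21, stayed between 17 and 24 in the settings that kept the preset correlation, and was 0 with an estimated correlation, 0 with the replicate block and an estimated correlation, 1 with fry and 4 with fry for either direction. DNA replication and S phase reversed to a median of 0.023 with quantile normalization, within the central range of random lists matched on signal in both settings. The lowest correlation between same-numbered arrays, 0.27, was 0.49 with normexp, and the cause of this move was not tested. Causes of the other moves were not tested either, apart from the exchange of the prior and the signal-dependent trend for the lower lists. Scan as a block was not run because it is the same as slide. Genes dim in both groups are limited by signal over background, and p45-/- array 1 had the lowest signal.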

Other observations

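The tests of explanations and the splits in this part were chosen after the results were seen, while the calls after quantile normalization they draw on were planned. For the random lists drawn after quantile normalization the bounds were set before their values were seen. Of the genes in this part, Gp6, Slc6a4, Ttll11, Hsd3b1, Mpig6b, Tbxas1, Matn1 and Nfe2 fall under the naming rule, and the others were chosen after their values were seen. Several erythroid and embryonic globin transcripts had large differences without passing the test over all genes. Hbb-bh1, an embryonic beta-like globin gene, differed by 2.96 (SE 0.76) and was higher on every p45-/- array than on any WT array, and Hbb-y differed by 2.02 (SE 1.00), with near-identical globin copies leaving each gene's share uncertain. Klf1, an erythroid transcription factor gene, differed by 2.32 (SE 0.54). Leaving out replicate 1 of both groups, 18 genes were lower and 6 higher, among them Dgkg (-4.29, adjusted p = 0.0261), Kcnf1 (-4.19, adjusted p = 0.0310) and Dusp14 (-3.24, adjusted p = 0.0480) on the lower side and Adgrg2 (3.25, adjusted p = 0.0479) on the higher. Hsd3b1, Mpig6b and Tbxas1 were also called lower there (limma adjusted p = 0.0261, 0.0261 and 0.0466), and Matn1 higher (limma adjusted p = 0.0397).

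The replicate 1 arrays of both genotypes differed from replicates 2 and 3 in the same direction for several lists. The median of the platelet surface receptors was -1.30 in WT array 1 and -1.40 in p45-/- array 1 relative to the other arrays of the group. For cholesterol synthesis these medians were -1.79 and -2.07, and for the erythroid markers 0.92 and 0.84. The interferon response genes lay at 2.03 in WT array 1 and 0.22 in p45-/- array 1.

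Xist, the transcript of the inactive X chromosome, was well above background on p45-/- arrays 1 and 3 and WT array 3, at 2.79, 3.35 and 3.36. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were well above background on the other 3 arrays and on none of these. Eif2s3y lay at 1.88, 1.64 and 1.72 on p45-/- array 2 and WT arrays 1 and 2. Arrays with the same number therefore differ in this for replicate 1 and match for replicates 2 and 3. None of these genes passed the filter of the genotype comparison, so the list of sex-linked genes had 0 tested members and no result.

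Of the 10 splits of the 6 arrays into 3 and 3, all 10 gave at least the 0 genes of the genotype split, and the highest other gave 3 genes, Ddx3y, Eif2s3y and Xist, in the split that parts the arrays by Xist. For the lists the genotype split gave 21 and the other splits 8 to 20, and 1 of the 10 splits reached 21. The test at the preset correlation thus called lists in every split, so a call alone does not mark the genotype. With 10 splits no share under 0.05 is possible. With the replicate block 1 of the 4 splits that part all 3 pairs gave 5 genes, the genotype split, and the highest of the others gave 0, and 4 splits are likewise too few.

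The first pattern weighed is the loss of Gp6, Clec1b, Slc6a4, Ttll11 and Fam131a. A lower share of megakaryocytes would take other platelet genes down as far, but the platelet surface receptors had a median of -0.58 with quartiles of -0.82 and -0.32, against a smallest fall of -4.07 among the 5. The falls were also there in pairs 2 and 3, where the smallest was -4.09. The blocked fit passes genes that fall alike in all pairs, so the selection set this, and it does not weigh the low signal of the replicate 1 arrays. A signal-dependent trend between arrays is argued against by quantile normalization, after which the smallest fall was -4.29. That setting ended the calls while the falls stayed (Gp6 from -6.09, SE 0.30, to -6.24, SE 0.34), and with the prior degrees of freedom set back from 2.04 to 4.05 all 5 were called again, so the weaker prior ended the calls. Loss of p45 is left as a hypothesis. The known p45 targets had a median of -1.40, below the -0.52 that is the 2.5th percentile of 10000 random lists matched on signal. Of the 18 lists called lower, 13 lay below their own such range, glycolysis among them. This position therefore does not weigh for loss of p45 over other sources. The random lists also leave out any correlation within a list. Chance is left open by the few splits, and the Nfe2 probe does not check the labels.

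The second pattern is the higher erythroid markers, at a median of 1.52 with quartiles of 0.57 and 2.27. A signal-dependent trend is argued against by random lists matched on signal, of which all but the highest 2.5% had a median of at most 0.171. A lower share of megakaryocytes would raise the markers of the other cell types alike, but the neutrophil markers had a median of -0.81 with quartiles of -0.92 and -0.70. The medians were also below 0 for mast cell (-0.86), stem cell (-0.40) and macrophage markers (-0.11). They were above 0 for hepatoblast (0.92), lymphoid (0.64), stromal (0.56) and endothelial markers (0.29). A lower share is therefore argued against as the only source, and a part in the rises is left open. More erythroid cells in the p45-/- cultures are left open as a source. Of the 24 markers, 18 were higher in both pairs 2 and 3, but 3 were lower in both. The 18 are part of the pattern itself, so they do not weigh for this source. Hba-a1, at 7.25 in WT, overlapped between the groups, and whether its high level hides a rise was not tested. More erythroid cells and a change of these transcripts within megakaryocytes cannot be told apart here, because no count of cells is at hand.

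The third pattern is the 18 lists lower at the preset correlation, against a trend in which dim genes lay higher and bright genes lower in the p45-/- arrays: in the dimmest of 10 equal bins of signal the median difference was 1.03 (1.49, 1.05 and 0.377 in pairs 1, 2 and 3) and in the brightest -0.26 (-0.625, -0.084 and -0.064), and quantile normalization left 0.27 and 0.045 there and -0.18 in the middle. Beyond the trend at their signal lay 11 lists, called lower after quantile normalization at the preset correlation and below the central range of random lists matched on signal before and after it. The CNC factors (median from -0.377 to -0.343, percentile 1.99 of the random lists) and NADPH production (from -0.428 to -0.42, percentile 1.0) were called after it and lay below the range only then. The random lists hold genes drawn singly, so their range leaves out the correlation within a list, at a median estimate of 0.454. It is too narrow for correlated genes, so the trend joined with variation between arrays that a list's genes share is not excluded. The transcription factors (from -0.44, quartiles -0.862 and -0.253, to -0.285, quartiles -0.544 and 0.020) and the unfolded protein response (from -0.477, quartiles -0.636 and -0.171, to -0.196, quartiles -0.347 and 0.0079) were below the range before and after, at percentiles 0.25 and 0.67, but their calls ended as the differences shrank, so the trend may account for at least part of them. It may account for the proteasome subunits (from -0.324 to -0.031) and DNA replication (from -0.236 to 0.023), within the range before and after and not called after, and the Nrf2 targets (from -0.246 to -0.137, adjusted p = 0.0452 after) stay open, still called but within the range. Without replicate 1 of both groups, 17 of the 18 lists were still called lower at the preset correlation. That test also called lists in other splits, so these calls do not exclude the low signal of the replicate 1 arrays. Some medians shrank there, from -0.246 to -0.0041 for the Nrf2 targets and from -0.548 to -0.262 for the apoptosis regulators. Others changed little, from -0.733 to -0.703 for the cytoskeleton and from -0.349 to -0.379 for mitosis. No biological explanation was tested for this pattern.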
